A study of Homo sapiens with 6 samples.

How the data were processed

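BPH-1, an epithelial cell line derived from human benign prostatic hyperplasia, was transduced with lentiviral shRNA that was either scrambled or directed against COX-2, the cyclooxygenase encoded by PTGS2. There were 3 libraries per group. Per the labels' protocols, total RNA was extracted with Trizol and chloroform, and stranded libraries were made after depletion of ribosomal RNA. Samples were grouped by the label of the lentiviral shRNA. The labels did not say that the libraries of a group came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

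The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for 16007 features, with 1 column per library and a merged FPKM for each group. The submitters' processing notes named TopHat and Bowtie2 and the human builds hg19 and GRCh37; their versions and the program that estimated the FPKM were not given in the sources used here. The deposited table also held the authors' log2 fold change, which equalled the log2 ratio of the merged values within 0.001 in 99.1% of the features with both merged values above 0. In 141 further features it was listed as 0 although the merged values differed, and in 194 it was infinite. The merged FPKM lay more than 1.5 times away from the mean of the 3 libraries in at least 1 group for 1238 features (7.7%), so the fits used the values of the single libraries. No column remained unmatched to a sample. Loci are given as the deposited table lists them, and its convention for the first base was not stated.

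Of the features, 12131 had a gene name and 3876 (24.2%) had none. A total of 11540 names stood on 1 feature, and 130 names were shared by 591 features that carried the same locus, so a value under a shared name is the value of a fragment of the locus and is uncertain as a measure of the gene. The highest library of each feature was at least 1.01 FPKM, so features below that level in all libraries were not analysed here. Values of exactly 0 were taken as listed at 0, and no fold was given against them.

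The design written before the data were examined foresaw a count model. The file held FPKM, so the fallback in that design was used. Features with a mean of at least 1 FPKM in either group were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance (trend) and all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p in the text comes from limma with this adjustment. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given as shCOX2 minus scrambled. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

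The genes named were fixed before the data were examined. They were PTGS2, the 10 named features with the largest rise and the 10 with the largest fall among those past the threshold whose libraries did not overlap between groups, up to 4 members of each gene list past the threshold, and a fixed set that included ESR1, ESR2, SRD5A1, SRD5A2, SRD5A3 and PTGS1; 1 further item of that set is not reported here. Other genes are given as members of a list, or were chosen after their values were seen, as stated. A total of 35 gene lists had been fixed before the data were examined, and 29 of them had at least 5 measured members on single-name features. These were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose p tests whether the genes of a list move, on balance, one way. Counts per list were made over all features tested and adjusted over the list alone.

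No read totals were in the table, so the depth was unknown and no counting interval is given. In the 400 lowest unnamed features the ratio of 2 libraries clustered at one value, which gives what 1 fragment was worth. That value differed by 1.11-fold, 1.13-fold and 1.02-fold between the scrambled libraries and by 1.1-fold between shCOX2 replicates 1 and 3. For shCOX2 replicate 2 against replicates 1 and 3 the clusters lay at 3.52-fold and 1.6-fold. For these pairs and across groups the clusters could not be told from small whole multiples of each other. No pair of libraries held identical values. The closest pair, shCOX2 replicates 1 and 3, differed by over 2-fold in 1.7% of 5998 single-name features with a mean of at least 5 FPKM.

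The fit was tested on simulated data with the means and spread of the 15725 tested features of this comparison and 200 planted changes. These were planted only in features with a mean log2(FPKM + 1) above 3, so the shares do not hold for low genes. Features were drawn independently, whereas those of a real library deviate together, so the calls among unchanged features do not give the false calls expected here. It recovered 1.5% of planted changes of 1 on the log2 scale, 3% of those of 2 and 30.3% of those of 3, with 2 calls among the unchanged features. With the spread of the scrambled libraries alone the shares were 6%, 22.4% and 59.1%. A planted shift of 1 list was found with both forms of camera, but the genes were simulated independently of each other. In the data the estimated correlation was 0.413 in the NF-kB and inflammatory list and 0.709 in the antigen presentation list. The simulation therefore does not show that camera at an estimated correlation could find such a shift here.

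Alternatives were other pseudocounts, filters and thresholds, the replicate number as a block, and each library left out in turn. After the data were seen, these were added: other scalings, features with 1 name only, features whose merged value matched, both shCOX2 replicates 1 and 3 left out, and removal of a spline trend over transcript length and GC content, with the gene lists then also tested at an estimated correlation. Length and GC were those of the longest GENCODE 29 transcript of each symbol and were known for 94.4% of single-name features; only these properties, and which small RNA genes lie inside a gene, were taken from that annotation, which is on another build than the loci.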

Results

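RNA sequencing compared BPH-1 prostate epithelial cells carrying an shRNA against COX-2 with the same cells carrying a scrambled shRNA, with 3 libraries in each group. The question, as far as the series title states it, concerned COX-2, estrogen receptor beta and inhibition of 5-alpha-reductase in these cells. The table gave FPKM for 16007 features, of which 15725 passed the filter on low values. The features summed to 4000000, 8270000 and 6890000 FPKM in scrambled replicates 1 to 3, and to 2410000, 5490000 and 2730000 FPKM in shCOX2 replicates 1 to 3. No read totals were given, so the depth was unknown. Features without a gene name held 81.1% to 90.7% of these sums. Between 13319 and 13753 features reached 1 FPKM in a library.

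PTGS2, the target of the shRNA (chromosome 1, 186640943 to 186649559, hg19), was at 0.728, 0.884 and 1.27 FPKM in the scrambled libraries. It was at 1.19, 0.415 and 2.46 FPKM in the libraries labelled shCOX2, so it was below every scrambled library in replicate 2 only. The mean was 0.961 ± 0.281 FPKM (SD, n = 3) with the scrambled shRNA and 1.35 ± 1.03 FPKM (SD, n = 3) under the shCOX2 label, a log2 fold change of 0.18 (SE 0.36, limma adjusted p = 0.693). The authors' deposited table gave merged values of 0.809 and 1.01 FPKM and a log2 fold change of 0.32. The deposited values therefore did not follow the label in replicates 1 and 3, and each direction below is that of the libraries labelled shCOX2. PTGS2 transcripts are AT-rich (36.9% GC, against a median of 48.8% among the tested genes), and replicates 1 and 3 read AT-rich genes higher. When a trend over transcript GC and length was removed, an alternative chosen after seeing the data, PTGS2 was lower in all 3 libraries labelled shCOX2: 0.26, 0.86 and 0.83 on the log2 scale against 1.32, 1.43 and 1.60 (log2 fold change -0.80, SE 0.21, limma adjusted p = 0.22). PTGS2 lay at 0.415 to 2.46 FPKM, where the added 1 compresses differences, whereas the trend was fitted over genes of all levels. The removal can therefore overcorrect PTGS2, so its lower values after it are uncertain.

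**Figure D1:**
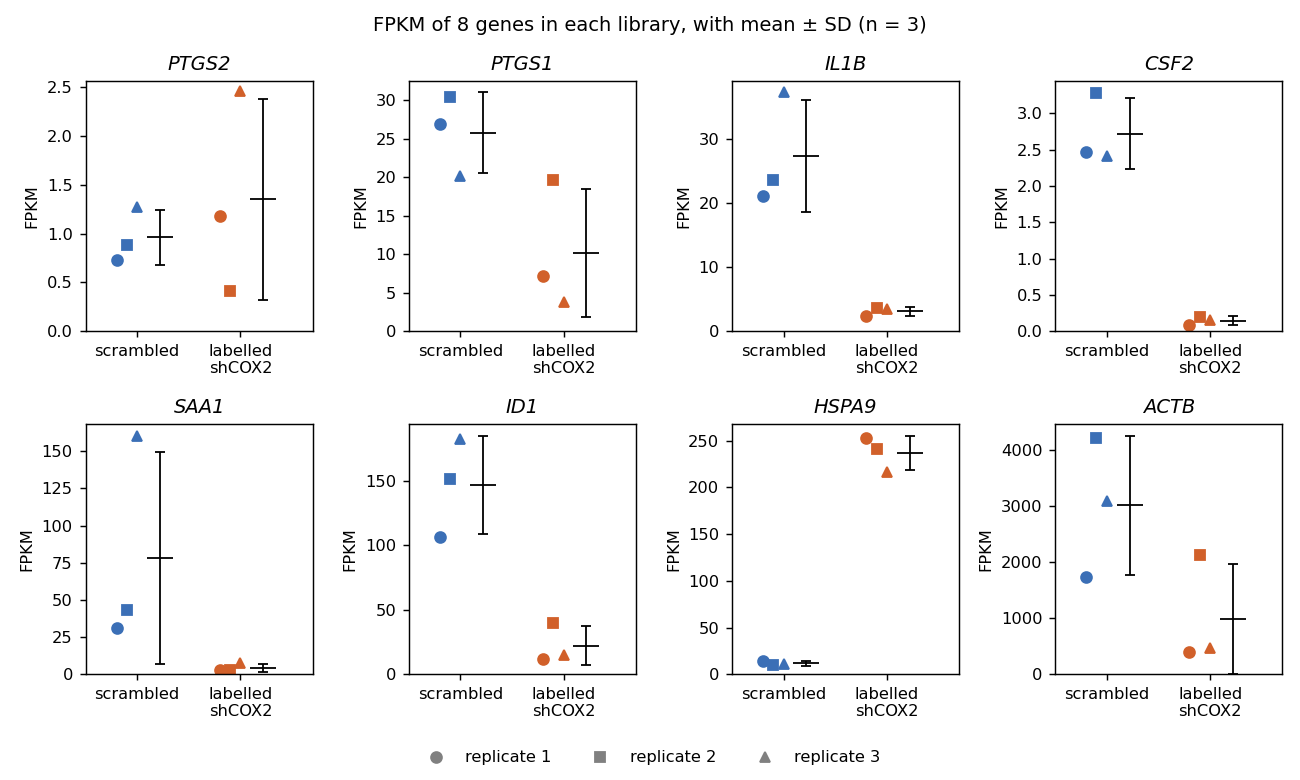
FPKM of 8 genes in each library (vertical axes start at 0 and differ between panels); points are single libraries, shaped by replicate number, and the bars beside them show the mean ± SD of 3 libraries. IL1B and CSF2 lay lower in all 3 libraries labelled shCOX2 than in any scrambled library and HSPA9 lay higher, while PTGS2 overlapped between the groups and ACTB was near the scrambled level in shCOX2 replicate 2 alone.

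The libraries labelled shCOX2 were not alike. Replicates 1 and 3 correlated with each other across features (Pearson r = 0.982), but with replicate 2 at 0.868 and 0.87 and with the scrambled libraries at 0.707 to 0.775. Replicate 2 correlated with the scrambled libraries at 0.906 to 0.915, and these with each other at 0.922 to 0.949; features are not independent replicates. The abundant transcripts ACTB and GAPDH were lower in replicates 1 and 3 than in any other library. ACTB was at 1737, 4201 and 3081 FPKM in the scrambled libraries and at 392, 2118 and 462 FPKM in shCOX2 replicates 1 to 3, and GAPDH was at 2027, 6023 and 4388 against 689, 3610 and 746 FPKM. The nuclear RNA MALAT1 was at 15.3, 12.5 and 14.8 FPKM in the scrambled libraries but at 169, 15.8 and 87.0 FPKM in shCOX2 replicates 1 to 3; these 3 genes were chosen after their values were seen. Against the mean of the scrambled libraries, the 1794 genes with the lowest GC content had medians of 1.33, 0.11 and 1.41 on the log2 scale in shCOX2 replicates 1 to 3, and the 1794 with the highest had -1.81, -0.38 and -1.70. The median log2 fold change over all tested features was -0.40, and over single-name features -0.48, so the changes below should be set against that shift.

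**Figure D2:**
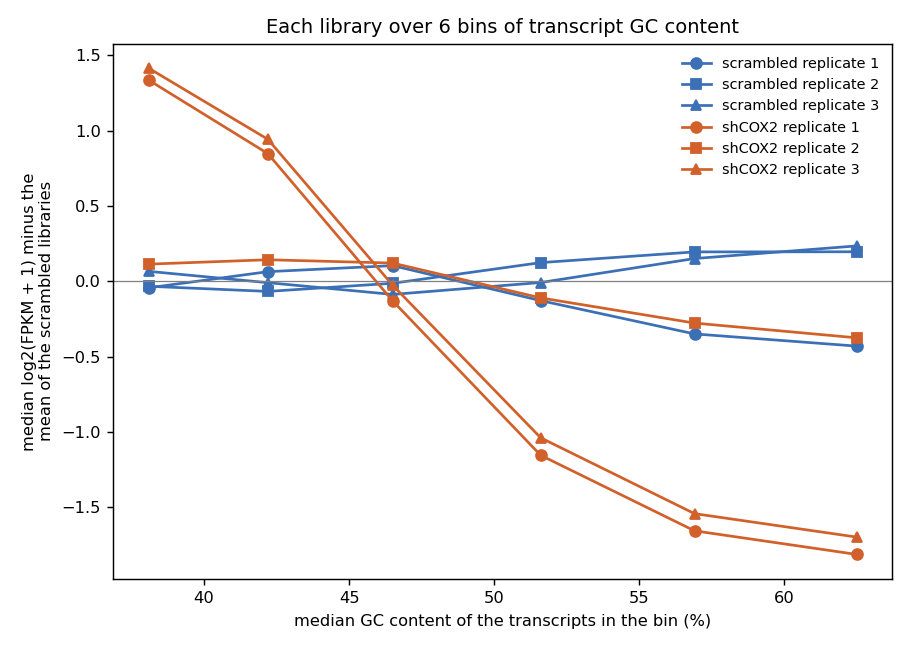
Median difference of log2(FPKM + 1) from the mean of the scrambled libraries (vertical axis) over 6 bins of transcript GC content (horizontal axis, percent); each line is 1 library. shCOX2 replicates 1 and 3 ran from 1.33 and 1.41 in the lowest bin to -1.81 and -1.70 in the highest, while replicate 2 ran from 0.11 to -0.38, close to scrambled replicate 1.

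IL1B, CSF2 and SAA1 fell under the shCOX2 label. IL1B, which encodes the cytokine interleukin-1 beta, was at 27.4 ± 8.74 FPKM (SD, n = 3) with the scrambled shRNA and at 3.14 ± 0.706 FPKM (SD, n = 3) under the shCOX2 label (log2 fold change -2.75, SE 0.42, limma adjusted p = 0.00593). CSF2, the gene of the growth factor GM-CSF, went from 2.72 ± 0.490 to 0.146 ± 0.0577 FPKM (-1.69, SE 0.27, adjusted p = 0.0077), and the acute-phase gene SAA1 from 78.3 ± 71.1 to 4.35 ± 2.62 FPKM (-3.63, SE 0.66, adjusted p = 0.0194). When the trend over transcript length and GC was removed, CSF2 was at -0.80 (adjusted p = 0.231) and SAA1 at -2.64 (adjusted p = 0.22). CSF2 was at 0.0848, 0.199 and 0.155 FPKM in shCOX2 replicates 1 to 3, where the added 1 compresses differences. The removal can overcorrect such low genes, so the smaller value does not give the share of the CSF2 fall due to the trend. With a pseudocount of 0.1 and no removal, CSF2 was at -3.53 (adjusted p = 0.0127). The largest rise on a single-name feature with a value above 0 in all libraries was that of HSPA9, the gene of a mitochondrial chaperone, from 11.7 ± 2.44 to 237 ± 18.6 FPKM (4.24, SE 0.50, adjusted p = 0.000901).

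In all, 299 of 15725 features passed the threshold, 244 of them higher and 55 lower under the shCOX2 label (81.6% higher). Of these, 225 had no gene name, and the 74 named ones comprised 42 features higher under 28 names and 32 features lower under 32 names. An unadjusted p under 0.05 was reached by 6659 features, and the groups did not overlap in 4939 (31.4%). Chance gives 10% only as an average over all ways to divide the libraries into equal groups. Features of a library deviate together, so the share under any single division can lie far from that average. The share was not computed for other divisions, so 31.4% cannot be read as an excess over chance. The count of features past the threshold rested on which libraries entered. Without shCOX2 replicate 2, whose spread from the other replicates enters the error, 11273 features passed. The balance of directions turned over in that fit, with 4154 higher and 7119 lower.

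Among the named falls, FAM20C, the gene of a kinase of secreted proteins (chromosome 7, 192786 to 301185), went from 56.3 ± 4.41 to 6.54 ± 3.80 FPKM (SD, n = 3; -3.03, SE 0.49, adjusted p = 0.00924). ID1, an inhibitor of differentiation factors, went from 147 ± 38.3 to 22.2 ± 15.1 FPKM (-2.83, adjusted p = 0.0476), and PYROXD2 from 73.0 ± 37.5 to 3.19 ± 2.11 FPKM (-4.09, adjusted p = 0.00386). TNFAIP2 fell by 2.58 on the log2 scale (adjusted p = 0.0263). Loci with small RNA names made up most of the other large falls. SNORD116-24 was at 22.6, 78.9 and 161 FPKM in the scrambled libraries and at 0, 0 and 0.00829 FPKM under the shCOX2 label. The locus named both MIR664 and SNORA36B was at 33.6, 18.7 and 19.0 against 0.373, 0 and 0.273 FPKM, MIR3648 fell by 4.53 (adjusted p = 0.0476), and the locus shared by MIR4315-1 and PLEKHM1P fell by 3.20 (adjusted p = 0.017); a locus with 2 names cannot be assigned to either gene. Without any 1 of the 6 libraries, IL1B, PYROXD2, SNORD116-24, the MIR664 locus and HSPA9 remained past the threshold. The calls of ID1, TNFAIP2, TGFBI, HLA-DRB1 and ALDOC were lost in 5 of these 6 fits, those of MIR3648 and the MIR4315-1 locus in 4, those of NGFR and LTB in 3, that of FAM20C in 2 and those of SAA1, CSF2, SNORD90 and KIAA1244 in 1, with the direction kept in each. Each of these fits kept at least 1 of the similar shCOX2 replicates 1 and 3. With both left out, which leaves 1 shCOX2 library, IL1B was at -2.565, PYROXD2 at -3.32 and SNORD116-24 at -6.072. The MIR664 locus was at -4.577 and HSPA9 at 4.27. A lone library gives no spread of its own, so whether these calls rest on that pair was not settled.

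The named rises were mostly features listed at 0 or near 0 in the scrambled libraries. The feature with the largest rise carried the name ERBB2IP, shared by 11 features, and was at 0 FPKM in all 3 scrambled libraries and at 290, 518 and 191 FPKM under the shCOX2 label. A feature named RHOT1, shared by 13, was at 1.67, 0 and 0 against 138, 75.4 and 129 FPKM. One named LRBA, shared by 38, was at 1.47, 1.01 and 0 against 114, 8.27 and 259 FPKM; its call was lost in 2 of the 6 fits without 1 library. A feature of VPRBP, shared by 17, was at 0 FPKM in all 3 scrambled libraries and at 14.1, 21.2 and 27.2 FPKM under the shCOX2 label (adjusted p = 5.72e-05). The features with the largest rise under the names ATP7A, TRIM2 and KIAA1244 were each listed at 0 in 2 scrambled libraries. They rose past the threshold (adjusted p = 0.000926, 0.000197 and 0.0127), and these names were shared by 15, 10 and 14 features. Further features named ERBB2IP, RHOT1, LRBA and ATP7A also rose past the threshold, some of them listed at 0 in all 3 scrambled libraries. Single-name MIR765 was at 0 in the scrambled libraries against 15.4, 36.3 and 11.3 FPKM, and SNORD90 at 0 against 6.77, 47.7 and 7.43 FPKM. The loci listed under these names spanned 110748 and 61396 bp, and that of MIR664 and SNORA36B 399225 bp, far longer than a small RNA, so these values are uncertain as measures of the small RNA. SNORD116-24 spanned 94 bp (chromosome 15, 25339182 to 25339276). Of the 244 higher features, 77 were listed at 0 in all 3 scrambled libraries and 34 carried a name shared by several features. Restricted to the 11401 features with a name of their own, 17 passed, 41.2% of them higher.

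When the trend over transcript length and GC was removed, 9 of 10762 genes passed, against 16 of the same genes before. Of the 9, IL1B (-2.72, SE 0.25, adjusted p = 0.0157), TGFBI (-1.56, SE 0.17, adjusted p = 0.0321), the vitamin D hydroxylase gene CYP24A1 (-1.56, SE 0.17, adjusted p = 0.0321), SNORD116-24, HSPA9 (3.78, SE 0.24, adjusted p = 0.00242), F8 and MIR765 were also past the threshold as deposited over all features, though TGFBI and CYP24A1 were not over the same genes alone (adjusted p = 0.0696 for each). S100A14 and SUSD4 passed only after the removal. The calls of CSF2, SAA1, LTB (-0.68), NGFR (-1.26), FAM20C (-1.77) and PYROXD2 (-3.02) held on these genes before the removal and ended with it. So did that of SNORD90 (adjusted p = 0.145), although its difference did not shrink, and it passed again with shCOX2 replicate 2 also left out (adjusted p = 0.0041), a fit in which 4174 of 10762 genes passed. Those of HLA-DRB1, ALDOC, TNFAIP2, ID1 and MIR3648 were already lost on these genes before it (adjusted p = 0.0657 to 0.0696), and were at -0.18, -1.26, -1.43, -1.49 and -3.15 after it. CSF2, LTB and HLA-DRB1 had means of 0.146, 0.446 and 0.373 FPKM under the shCOX2 label, where the removal can overcorrect.

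The NF-kB and inflammatory list was past the threshold with camera's preset correlation (adjusted p = 0.000709), but not with an estimated correlation (adjusted p = 0.754) or with fry (adjusted p = 0.0701). Of 21 measured members, 19 had a negative log2 fold change and 5 fell past the threshold over all genes (IL1B, CSF2, LTB, TNFAIP2 and ICAM1); 13 were lower when adjusted over the list alone, and none was higher by either count. The lymphotoxin gene LTB went from 5.11 ± 2.40 to 0.446 ± 0.406 FPKM (SD, n = 3; -2.04, adjusted p = 0.0199), and the adhesion gene ICAM1 from 43.9 ± 13.2 to 7.76 ± 3.97 FPKM (-2.42, adjusted p = 0.0443). NFKB2 and CXCL3 passed over the list alone (adjusted p = 0.00693 and 0.00946), whereas IL1A and IL8 had log2 fold changes of -0.18 and 0.04. The median of the list was -1.20, with -1.77, -1.11 and -1.17 in shCOX2 replicates 1 to 3 and -0.42, -0.25 and 0.69 in the scrambled libraries. The list was no longer past the threshold without shCOX2 replicate 2 (camera adjusted p = 0.096). Camera sets a list against the other genes, and the median log2 fold change over all tested features was -0.598 in that fit, against -0.402 with all libraries. That p therefore does not tell how far the list itself fell.

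Antigen presentation genes were the other list past the threshold (17 measured, 16 with a negative log2 fold change, median -1.47, camera adjusted p = 0.00785, but adjusted p = 0.754 with an estimated correlation and 0.0701 with fry). Its median was -2.02, -0.69 and -1.58 in shCOX2 replicates 1 to 3 and -0.38, -0.12 and 0.54 in the scrambled libraries. HLA-DRB1 alone fell over all genes tested, from 2.62 ± 0.853 to 0.373 ± 0.133 FPKM (SD, n = 3; -1.38, adjusted p = 0.0453), and 13 members were lower when adjusted over the list alone. These included HLA-B (458 ± 163 against 118 ± 35.2 FPKM) and the immunoproteasome gene PSMB9 (81.1 ± 28.3 against 19.5 ± 14.4 FPKM); reads of HLA genes can be shared between near-identical copies. B2M, the light chain of class I molecules, went the other way without passing, at 194, 139 and 306 FPKM against 446, 157 and 709 FPKM. The list had camera adjusted p = 0.0927 without shCOX2 replicate 2, again set against other genes that were lower as a whole. It had camera adjusted p = 0.219 among features with a mean of at least 5 FPKM. On the deposited values, no list of the 29 passed with an estimated correlation or with fry.

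**Figure D3:**
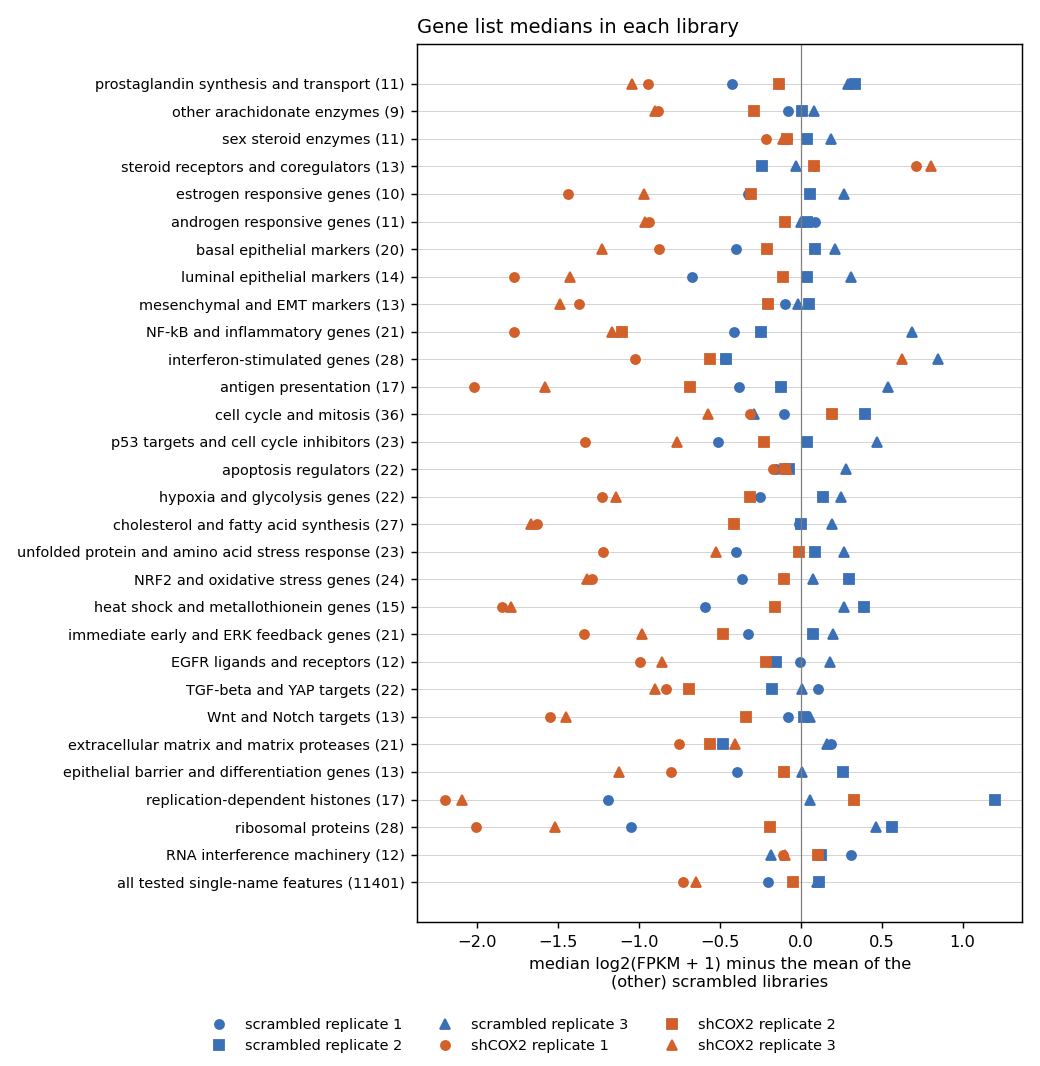
Median of each gene list (number of measured members in brackets) in each library, as log2(FPKM + 1) minus the mean of the scrambled libraries, or of the other two for a scrambled library. The NF-kB and inflammatory list lay at -1.77, -1.11 and -1.17 in shCOX2 replicates 1 to 3, while replicate 2 lay at -0.05 over all single-name features.

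In the prostaglandin synthesis and transport list, none of 11 measured genes passed over all genes and 1, the prostaglandin E synthase gene PTGES, was lower when adjusted over the list alone (37.0 ± 17.7 against 7.65 ± 4.83 FPKM, SD, n = 3; -2.16, adjusted p = 0.0365 over the list and 0.106 over all genes). The list had camera adjusted p = 0.452. PTGS1, which encodes COX-1, was at 26.8, 30.4 and 20.1 FPKM in the scrambled libraries and 7.19, 19.6 and 3.81 FPKM under the shCOX2 label (-1.50, SE 0.57, adjusted p = 0.109). It passed without shCOX2 replicate 2 (-2.07, adjusted p = 0.0035), a fit in which 11273 of 15725 features passed. The authors' deposited table gave PTGS1 merged values of 22.1 and 9.68 FPKM with a log2 fold change of 0. SRD5A1, a 5-alpha-reductase gene, was at 6.49 ± 1.12 and 7.02 ± 0.441 FPKM (SD, n = 3; 0.11, SE 0.36, adjusted p = 0.816), but was lower with the length and GC trend removed and shCOX2 replicate 2 left out (-0.65, adjusted p = 0.0202), a fit in which 4174 of 10762 genes passed. ESR1, ESR2 and SRD5A2 were not analysed here, and SRD5A3 was below the filter. The sex steroid enzyme list (11 measured, median -0.08, adjusted p = 0.718), the steroid receptor and coregulator list (13, 0.48, adjusted p = 0.33), the estrogen responsive list (10, -0.88, adjusted p = 0.447) and the androgen responsive list (11, -0.71, adjusted p = 0.683) did not pass.

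Epithelial, mesenchymal and metabolic lists did not pass as groups, with 1 fallen member in some. The nerve growth factor receptor gene NGFR fell among 20 basal markers, from 14.4 ± 3.72 to 1.88 ± 1.23 FPKM (SD, n = 3; -2.47, adjusted p = 0.0136; list adjusted p = 0.596). TGFBI, a matrix protein gene, fell among 13 mesenchymal markers, from 19.6 ± 0.193 to 3.94 ± 1.88 FPKM (-2.12, adjusted p = 0.0309; list adjusted p = 0.0706). The aldolase gene ALDOC fell among 22 hypoxia and glycolysis genes (-2.46, adjusted p = 0.0436; list adjusted p = 0.201), and ID1 among 22 TGF-beta and YAP targets (list adjusted p = 0.12). The cholesterol and fatty acid synthesis list had 11 lower and 2 higher of 27 genes when adjusted over the list alone, and none over all genes (median -1.20, mean -0.57, list adjusted p = 0.447). The 36 cell cycle genes had 16 positive and 20 negative log2 fold changes (median -0.07, adjusted p = 0.42). The 28 ribosomal protein genes had a median of -1.31 (adjusted p = 0.143), with -2.01, -0.19 and -1.52 in shCOX2 replicates 1 to 3.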

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

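The scalings, the feature subsets, the length and GC correction and the fit without shCOX2 replicates 1 and 3 were chosen after seeing the data; the rest were planned. The main values were 299 features past the threshold, 244 higher and 55 lower, and 2 gene lists. Count models and other count scalings were not run because the file holds FPKM, and those planned for a table of the authors' comparison alone were not run because it holds single libraries. Without 1 library each, features past the threshold ranged from 246 to 11273, higher ones from 193 to 4154, lower ones from 14 to 7119, the log2 fold change of PTGS2 from -0.15 (without shCOX2 replicate 3) to 0.50 and lists from 0 to 5; the highest counts and 0 lists all came without shCOX2 replicate 2. With both replicates 1 and 3 left out, 144 features passed, 143 higher and 1 lower, with 11 lists, and PTGS2 was at -0.46; the lone library was assumed to vary like the scrambled ones.

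A pseudocount of 0.1 left 35 lower features, and one of 0.01 left 135 in all, 124 higher and 11 lower. A mean of at least 5 FPKM left 31 lower and 1 list. A threshold of 0.01 left 194, of which 9 lower, and one of 0.1 gave 137 lower. Centring on the median named gene left 32 lower. Features with 1 name gave 17 (7 higher, 10 lower), those with a length and GC 16 (7 and 9), and those whose merged FPKM matched 89 (73 and 16), with fewer features tested in each. The length and GC correction gave 9 (5 higher, 4 lower) and 5 lists, and with shCOX2 replicate 2 also left out 4174 (2260 and 1914). An estimated correlation left 0 lists, with or without the length and GC correction, and all features as background gave 5. With the replicate number as a block, 6985 features passed, 2702 higher and 4283 lower, and the lists stayed at 2. Whether the numbers pair the samples could not be settled. Deviations of same-numbered libraries from their group mean correlated at 0.31, 0.36 and 0.05. For shCOX2 replicates 1 and 2 the same-numbered scrambled library correlated best, but shCOX2 replicate 3 correlated best with scrambled replicate 1 (0.27). The 3 deviations within a group depend on each other, so these correlations are weak evidence either way.

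PTGS2 was reversed at -0.80 by the correction and at -0.90 (adjusted p = 0.0138) with replicate 2 also left out; its adjusted p ranged from 0.0138 to 1 over all alternatives. SRD5A1 ranged from -0.003 (without scrambled replicate 3) to 0.21 without 1 library, and was reversed at -0.42 by the correction and at -0.65 (adjusted p = 0.0202) with replicate 2 also left out, and HLA-DRB1 at 0.24 in the last of these. In the corrected fit without replicate 2, 4174 of 10762 genes passed, so a call there says little about 1 gene. The GC trend that differs between libraries is removed by the correction's construction; the cause of the other changes was not tested. PTGS1 passed without shCOX2 replicate 2 (-2.07, adjusted p = 0.0035), with the correction and replicate 2 left out (-1.25, adjusted p = 0.0145) and with the replicate number as a block (adjusted p = 0.0139). Of 15725 features, 11273 passed in the first of these fits and 6985 with the block. CSF2 went from -1.69 to -0.80 with the correction and to -0.40 with replicate 2 also left out, and LTB from -2.04 to -0.68 and -0.38. Both genes lay below 1 FPKM in every library labelled shCOX2, where the correction can remove too much. Of 534 alternative log2 fold changes of named genes, 399 kept their direction and side of the threshold and 124 lost the call. Of 69 alternative counts of features and 23 of lists, 33 and 14 stayed within 1.5 times the main count. The depth is unknown, so what it limits cannot be given. Of changes of 2 on the log2 scale, planted in features with a mean log2(FPKM + 1) above 3, the fit recovered 3%.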

Other observations

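Interferon-stimulated genes moved apart between the libraries. Of 28 measured, 12 had a positive and 16 a negative log2 fold change (median -0.52, mean 0.06, camera adjusted p = 0.42), but the list median was -1.02 and -0.56 in shCOX2 replicates 1 and 2 and 0.63 in replicate 3. Scrambled replicate 3 also stood above the other scrambled libraries, by 0.85. IFIT2, chosen after its values were seen, was at 0.489, 0.320 and 1.30 FPKM in the scrambled libraries and at 6.63, 0.524 and 18.8 FPKM in shCOX2 replicates 1 to 3. The 17 histone genes had medians of -2.20, 0.33 and -2.09 in shCOX2 replicates 1 to 3 and of -1.19, 1.20 and 0.06 in the scrambled libraries (camera adjusted p = 0.143). After the trend over transcript length and GC was removed, 9 of 11 genes of prostaglandin synthesis had a negative log2 fold change (median -0.55, camera adjusted p = 0.049, but adjusted p = 0.653 with an estimated correlation and 0.262 with fry). Among them were PTGES (-0.95, SE 0.25, adjusted p = 0.22) and PTGS1 (-0.92, SE 0.35, adjusted p = 0.221), and no member passed the threshold. After it, 23 of 28 ribosomal protein genes had a negative log2 fold change (26 before; median -0.82 against -1.31 before), as had 13 of 22 TGF-beta and YAP targets (18 before; median -0.36 against -0.71 before). Relative to the other genes these lists then passed (camera adjusted p = 0.00139 and 0.049), but not with an estimated correlation (adjusted p = 0.721 and 0.653). The removal left 14 of 16 antigen presentation genes with a negative log2 fold change (median -0.52, camera adjusted p = 0.00139, but adjusted p = 0.653 with an estimated correlation). With fry the mesenchymal list alone passed (9 of 12 with a negative log2 fold change, median -0.49, fry adjusted p = 0.0329, camera adjusted p = 0.0621, and adjusted p = 0.653 with an estimated correlation). Unnamed features under 100 bp long held 75.9% to 85% of all FPKM in each library.

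The tests of the splits, of the length and GC trend, of a wrong label, of the list in replicate 2, of scrambled replicate 3 and of small RNA genes were chosen after the result was seen, in the last case after some of the risen genes were recognised as hosts of small nucleolar RNAs; the test of features that share a name was written before. Of the 10 splits of the 6 libraries into 3 against 3, the labelled split gave 299 features and the highest of the others 2. The labelled split was 1 of 10, and 10 splits cannot give a share under 0.05. At an unadjusted limma p under 0.05 it gave 6659 features, and the split of scrambled replicate 1 with shCOX2 replicates 1 and 3 gave 6224.

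shCOX2 replicates 1 and 3 stood apart from the other 4 libraries. After removal of a trend over GC and length, the correlation of replicates 1 and 3 with the scrambled libraries was 0.888 on average. It stayed below the 0.952 of the least similar scrambled pair, although it had ranged from 0.659 to 0.741 before. The removal used 1 transcript per gene and may be incomplete, so the trend as the whole cause stays open. A wrong label on replicate 2 is argued against only for a sample prepared like the scrambled libraries. The test below cannot exclude a wrong label on a scrambled sample prepared like replicates 1 and 3, which could share their features. A set of 85 features lay under 0.5 FPKM in the scrambled libraries and over 5 FPKM in replicates 1 and 3. Replicate 2 held 88.2% of them over 1 FPKM (95% exact interval 79.4% to 94.2%). Each left-out scrambled library had a set of its own, of 108 to 140 features chosen without it, and held at most 32.8%. Features are not independent, so the interval is too narrow. Part of the distance may therefore be a GC-related difference of RNA or library, the rest stays open, and so does the knockdown as a cause, because PTGS2 changed sign with the correction (0.18 and -0.80).

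The lower values of the NF-kB and inflammatory list were the second pattern. The high inflammatory genes of scrambled replicate 3 as its cause are argued against, since camera with its preset correlation gave adjusted p = 0.00215 without that library. With an estimated correlation the list did not pass with all 6 libraries (camera adjusted p = 0.754), and that form was not run without scrambled replicate 3. The GC and length trend as its whole cause stays open. After removal the list median was -0.75 (bootstrap interval over members -0.995 to -0.678, all genes 0.01). The interval resamples correlated member genes and holds no spread between libraries, so it is too narrow. Camera gave adjusted p = 1.27e-06, but adjusted p = 0.653 with an estimated correlation and 0.184 with fry. After removal 1 of 21 members was past the threshold, against 3 before among the same 10762 genes. Of the medians of shCOX2 replicates 1 to 3 (-0.87, -1.01 and -0.35) the last was not below the lowest scrambled library (-0.49). Whether the pattern goes beyond replicates 1 and 3 could not be settled: the median in replicate 2 was -1.11 before the removal, below the lowest scrambled library (-0.42), and the lowest of all 6 after it, but by less than the range of the scrambled libraries in both cases and in 1 library. Lower inflammatory signalling after loss of COX-2 remains a candidate explanation that these data do not test, because no other shRNA was used and the level of PTGS2 depended on the correction.

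The risen named features were the third pattern. A different split of a gene's reads over the features with its name would lower the others, yet the other 148 features of these 20 names had a median log2 fold change of 0.82 (bootstrap interval 0.68 to 1.03, 116 positive). Features of 1 name are not independent, so the interval is too narrow. A common rise of all features of these names could also hide such a split. Whether small RNA genes inside the named genes were the source stays open: of the 8 risen names on 1 feature, MIR765 and SNORD90 are small RNAs themselves and were left out, and 5 of the other 6 (83.3%; HSPA9, GNL3, WDR43, HBS1L and F8, but not C4orf27) held one, against 9.9% of 10632 other genes and 10.8% of 6029 with loci as long, but the explanation was found from these genes, so the count is no test of it. HSPA9 holds SNORD63, GNL3 holds SNORD19 and WDR43 holds SNORD53. The annotation cannot show which reads made the rise, and no biological explanation was tested.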
